A study of Rattus norvegicus and Mus musculus with 56 samples.

How the data were processed

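Messenger RNA of the lumbar dorsal horn was sequenced in 56 libraries, 32 from Sprague-Dawley rats and 24 from C57BL/6 mice. Per the labels, animals of both sexes had spared nerve injury (SNI) or sham surgery, tissue was taken on postoperative day 7 from the ipsilateral or the contralateral side, and poly(A) RNA was sequenced after column extraction. Sex, surgery and side give 8 groups in each species, with 4 libraries per group in rat and 3 in mouse. The labels state neither the number of animals behind a library nor which libraries share an animal.

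The deposited files hold, for each library, a gene identifier and the number of reads counted on it by the authors, with no normalization. All 56 were whole-number counts at or above 0. The submitters' processing notes name the aligner STAR and the builds GRCm38, mm10 and Rnor_6.0, without versions. The counting program, its strand setting and the annotation are not given in the sources used here. Each file ends with 5 entries that name no gene, laid out as a read counter's special classes, and these were kept out of library sizes and tests. In rat they held 18.7% to 25.2% of all entries as reads in no feature (median 22.0%), 14.7% to 17.4% as reads without a unique position and 0.0664% to 0.0828% as ambiguous reads. In mouse the shares were 12.3% to 15.8% (median 14.2%), 9.92% to 12.8% and 0.370% to 0.418%. The low-quality and not-aligned classes held 0% in both species.

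The main test fixed before the data were examined was a quasi-likelihood test on counts. The deposited tables are separated by tabs under a comma-separated file type, and the format check that decides which tests may be run could not read their number column as counts. The column was therefore recorded under no standard unit, and limma's trend method on log2 CPM, counts scaled to a common library total, took the place of the count test. The values themselves are read counts, and the count-based test was not run. This replacement was made after the tables had been opened and before any comparison was computed.

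Within each species, library sizes were scaled by the trimmed mean of M-values (TMM), trimming 30% of ratios and 5% of levels. The TMM factors lay between 0.941 and 1.05 in rat and between 0.950 and 1.04 in mouse. Genes were kept that reached about 10 counts, scaled to the median library, in as many libraries as the smallest group holds, with a total of at least 15. Log2 CPM was computed with a prior count of 2, so fold changes of genes with few reads are understated. Linear models of group means were fitted in limma 3.58.1 (R 4.3.3) with robust empirical Bayes moderation and a mean-variance trend. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and a gene was called at an adjusted p under 0.05. Errors of log2 fold changes are standard errors (SE) from the model. Levels are CPM as mean ± SD over libraries.

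Ipsilateral and contralateral libraries were fitted separately for the effect of SNI over sham, averaged over the sexes, in each sex, and as a sex by surgery interaction. The side by surgery interaction and the side differences within SNI and within sham used all 8 groups of a species. Males and females were compared in ipsilateral sham libraries. Chi-square comparisons of counts within groups gave 12.7 to 99.1 per degree of freedom over 48 rat pairs and 6.10 to 31.4 over 24 mouse pairs, so no libraries were treated as duplicates. Files and figures were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

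For mice, 38 gene lists of cell types and pathways were fixed before the data were examined. Each was tested with limma's camera, which compares a list's members with all other genes, at a preset correlation of 0.01 and again with an estimated correlation. Limma's fry, which asks whether the members move one way on balance without setting them against other genes, was run beside it. List p-values were adjusted over the 38 lists of a comparison. Calls of members are given over all genes tested and adjusted over the list alone.

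Named genes followed a rule fixed before the data were examined. It took the 15 genes called higher and the 10 called lower with the smallest p in the ipsilateral comparison averaged over the sexes, the 5 of each direction in each sex, the 6 of each interaction, the 5 of the sex comparison, and 3 members of each list. Atf3, Sprr1a and the interaction of Irf7 were named outside the rule, after their values were seen. So were these further list members: Sall1, Tmem119, Cx3cr1, Fcgr2b, P2ry6, P2rx4, Bdnf, Cst7, Itgax, Apoe, Spp1, Lpl, Itgb2, C3ar1, C3, Gfap and Cyp51. The results of 2 genes under the rule are not reported here. Mouse symbols were matched by identifier for 40254 of 41388 identifiers, which hold 99.8% of the gene reads, and positions are those of the mouse annotation on GRCm38. The files do not pair the 32545 rat identifiers with names, so the rat gene lists, the rules that need rat names and every gene-by-gene comparison of the species were not analysed here.

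The procedure was tested on simulated counts drawn from the real means, with about 50 genes changed at each fold. Every gene had the same spread between libraries (dispersion 0.0104 in rat and 0.0037 in mouse). Genes were drawn independently and without sets of libraries. The recovery and false calls below hold for that setting, and real genes with a larger spread may be recovered less often. Averaged over the sexes, it recovered 98% of 1.5-fold and 100% of 2-fold increases among 15838 simulated rat genes, and 88% and 100% among 17498 mouse genes. For 1 sex, 1.5-fold increases were recovered at 88% (females) and 82% (males) in rat, and at 80% and 74% in mouse. Of the simulated calls, 5.26% were false in rat averaged over the sexes, 5.05% in females and 9.27% in males, where the adjusted p allows 5%, and 3.09%, 2.72% and 4.86% in mouse. The alternatives covered scaling, filters, voom weights, a minimum fold of 1.2, the libraries in the fit, extra model terms, blocks of neighbouring title numbers and leaving out each library.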

Results

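Poly(A) RNA was profiled in the dorsal horn of the lumbar spinal cord, where sensory nerve fibres end, 7 days after spared nerve injury (SNI) or sham surgery. SNI is a model of neuropathic pain in which branches of the sciatic nerve are cut and a neighbouring branch is left intact. The 32 rat libraries formed 8 groups of 4 and the 24 mouse libraries 8 groups of 3, each group combining sex, surgery and side. Gene reads per library ran from 20.4 to 49.4 M in rat (median 27.2 M) and from 27.98 to 42.9 M in mouse (median 32.6 M), with M for mega. Because the labels do not say which libraries share an animal or how many animals a library holds, p-values measure the spread between these libraries. The series was set up to compare the response to nerve injury between sexes and species, with pain-relieving agents in view.

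In mice, the first question was which transcripts differed on the operated side. Genes of microglia, the resident macrophages of the central nervous system, rose together after SNI. Olfml3, which encodes a secreted protein enriched in microglia, stood at 19.3 ± 1.01 CPM in female sham and 40.5 ± 5.92 CPM in female SNI libraries (SD, n = 3 each). In males it stood at 18.3 ± 2.25 and 49.6 ± 3.59 CPM, and averaged over the sexes it rose 2.38-fold (log2 1.25, SE 0.075, adjusted p = 9.9e-07). C1qa, a chain of the complement protein C1q, went from 29.97 ± 1.09 to 63.1 ± 9.79 CPM in females and from 32.5 ± 4.43 to 79.0 ± 3.92 CPM in males (2.26-fold, adjusted p = 2.7e-06). Olfml3 (ENSMUSG00000027848) lies on chromosome 3 at 103722222 to 103738001 and C1qa (ENSMUSG00000036887) on chromosome 4 at 136895917 to 136898803 of GRCm38. All gene values here rest on reads per gene as the authors counted them, and the parts of a gene that were counted are not stated.

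Of 17 measured genes of the microglia identity list, 16 rose, and all 17 rose when p was adjusted over the list alone (median log2 fold change 1.02, camera adjusted p = 5.1e-48). The exception over all genes was the transcription factor gene Sall1, at 0.23. Tmem119 rose by 1.07, the fractalkine receptor gene Cx3cr1 by 0.96, and Csf1r, the receptor that microglia need for survival, by 1.02 on the log2 scale. Itgam, the integrin known as CD11b, rose 2.67-fold, but 68.7% of its exon length overlaps a predicted gene on the same strand. Csf1r overlaps another gene over 15.1% of its exon length, and reads in such stretches cannot be assigned with the counting unknown. The list's call held with an estimated correlation (adjusted p = 0.0489).

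Genes of ITAM and Syk signalling, the pathway behind activating immune receptors, moved with them. In that list 17 of 19 measured members rose, 18 adjusted over the list alone, among them the Fc receptor genes Fcgr1 (1.13) and Fcgr2b (1.12). The median was 0.91, and the call also held with an estimated correlation (adjusted p = 0.0489). Of 16 genes of microglial signalling linked to pain, 8 rose, 11 adjusted over the list alone, with a median of 0.54. Ctss, the protease cathepsin S, rose by 1.31 and P2ry6, a nucleotide receptor, by 1.08, while the ATP receptor gene P2rx4 stood at 0.09 and Bdnf at 0.07. In the list of Toll-like receptors and the inflammasome, 10 of 20 rose, 12 adjusted over the list alone, led by Ly86 at 2.96-fold. With an estimated correlation both of these lists had an adjusted p = 0.0581.

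Activated phagocyte genes split. Cst7 (1.63), Trem2 (1.17) and Itgax (0.99) were among 8 of 19 that rose, 11 adjusted over the list alone, whereas Apoe stood at 0.13, Spp1 at -0.09 and Lpl at -0.13. The list had a median of 0.39 and an adjusted p = 0.0589 with an estimated correlation. In the complement list, 5 of 16 rose, 6 adjusted over the list alone: the chains C1qa, C1qb and C1qc, and the receptor genes Itgb2 and C3ar1. C3 itself stood at -0.12, and the list had a median of 0.12 and an adjusted p = 0.316 with an estimated correlation. Of 9 chemokine genes, 3 rose over all genes and over the list alone, the monocyte attractants Ccl2 (1.81), Ccl7 (2.55) and Ccl12 (1.56). The chemokine list's adjusted p was 0.198 with an estimated correlation.

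The interferon response list had 3 of 21 members called, Irf7 (0.70), Bst2 (0.60) and Mx1 (1.28), and 8 adjusted over the list alone. Its median was 0.22, with an adjusted p = 0.247 under an estimated correlation. Of 15 antigen presentation genes, B2m rose (0.32), 7 adjusted over the list alone, with a median of 0.21 and an adjusted p = 0.240 under an estimated correlation. Serpina3n (0.45), Timp1 (1.36) and Cd44 (0.68) rose among 19 reactive astrocyte genes, 5 adjusted over the list alone. Gfap, the astrocyte filament gene, stood at 0.22 and was not called, and the list's adjusted p was 0.493 with an estimated correlation. No cell cycle gene among 19 was called by limma over all genes or over the list alone, and the list's median was -0.00 (camera adjusted p = 0.889).

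Genes known to respond to nerve injury in neurons formed the other group that rose. In the axon injury list 8 of 20 rose, 15 adjusted over the list alone, with a median of 0.47 and an adjusted p = 0.0579 with an estimated correlation. They included the orphan receptor gene Gpr151 (2.48), the neuropeptide genes Gal (1.25) and Npy (0.55), the transcription factor gene Sox11 (0.55) and the peptidase gene Ecel1 (0.54). Sprr1a and Atf3, a transcription factor induced in injured neurons, had log2 fold changes of 6.30 (SE 1.21, adjusted p = 0.0391) and 4.09 (SE 0.757, adjusted p = 0.0320). Atf3 lies on chromosome 1 at 191170296 to 191218039 and Sprr1a on chromosome 3 at 92483952 to 92485895; both were singled out after their values were seen. In 5 of 6 ipsilateral SNI libraries Atf3 stood at 15.2 to 74.5 CPM. In female SNI replicate 1 it stood at 1.02 CPM, beside 1.09 to 1.49 CPM in sham, and Sprr1a there stood at 0.229 CPM. Both calls were lost with voom weights and in most fits that left out 1 library, though not without female SNI replicate 1. With the motor neuron level in the model both calls were lost because the SE grew, with Atf3 at 4.70 (SE 1.01) and Sprr1a at 7.29 (SE 1.61).

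Few genes that analgesic drugs act on were called. Of 20 analgesic targets, the cyclooxygenase gene Ptgs1 rose (0.57), over all genes and over the list alone, and the list's median was 0.03 (camera adjusted p = 0.577). None of 20 glutamate receptor genes (median 0.01, camera adjusted p = 0.577, its direction downward) and none of 31 voltage-gated channel genes (median 0.00, camera adjusted p = 0.465) was called by limma. Of 20 genes for GABA and glycine receptors and chloride transport, Glrb, a glycine receptor subunit, fell by 0.20, 2 adjusted over the list alone; its call was lost in most fits that left out 1 library. That list had a median of -0.06 and was called lower by camera (adjusted p = 0.0014), with an adjusted p = 0.198 under an estimated correlation.

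Genes called lower numbered 23 and moved less; 2 genes were called lower with the motor neuron level in the model and 1 without the libraries highest in blood and neutrophil markers. Ano3, a membrane protein of the anoctamin family, went from 90.4 ± 2.30 to 82.1 ± 3.21 CPM in females and from 92.4 ± 1 to 73.3 ± 3.48 CPM in males (log2 -0.24, SE 0.037, adjusted p = 0.0017, n = 3 each). In the cholesterol synthesis list 4 of 15 fell, 8 adjusted over the list alone: Idi1 (-0.21), Msmo1 (-0.20), Insig1 (-0.16) and Cyp51 (-0.15). Msmo1, which encodes a sterol oxidase, went from 116 ± 6.50 to 97.4 ± 5.48 CPM in females and from 121 ± 6.56 to 109 ± 2.53 CPM in males. The list's median was -0.13 (camera adjusted p = 7.1e-07, adjusted p = 0.198 with an estimated correlation). Its mean log2 level went from 6.61 to 6.43 in females, the sex in which motor neuron genes fell more, and from 6.63 to 6.61 in males. Elovl6, a fatty acid elongase gene, fell by 0.17, and Mindy3, Osbpl1a, Kcne1l, Nudt12, Nr5a2 and Odr4 were the other named genes that fell, by 0.17 to 0.84.

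Markers of other cells moved beside these groups. Motor neuron genes had a median of -0.81 over 12 members, with none called over all genes and 1 adjusted over the list alone (camera adjusted p = 2.5e-05, adjusted p = 0.316 with an estimated correlation). Their mean log2 level was 4.01 ± 0.635 in female sham and 2.52 ± 0.378 in female SNI libraries, and 3.82 ± 0.788 and 3.71 ± 0.365 in males. Blood genes had a median of -0.90 over 6 members (camera adjusted p = 2.4e-05, adjusted p = 0.247 with an estimated correlation). Oligodendrocyte genes (-0.10, 15 members), heat shock genes (-0.11, 10 members) and mitochondrially encoded genes (-0.19, 13 members) were also called lower by camera. With an estimated correlation these had an adjusted p = 0.637, an adjusted p = 0.554 and an adjusted p = 0.240, and limma called none of their members.

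The remaining lists were not called by camera. Medians were 0.01 for 14 astrocyte identity genes, -0.01 for 10 oligodendrocyte precursor genes, -0.03 for 14 pan-neuronal genes and 0.07 for 18 genes of excitatory dorsal horn neurons. Inhibitory dorsal horn neuron genes had a median of 0.04 over 14 members, with Gal and Npy called. Dorsal root ganglion genes had a median of 0.10 over 8 members, with the sodium channel gene Scn9a called (0.97), and Schwann cell genes one of -0.01 over 12, with Ngfr called (0.89). Neutrophil genes had a median of -1.18 over 9 members, with a mean log2 level of 3.14 in female sham replicate 1, the highest ipsilateral library. The SD of that level within groups was 1.35. Csf3r, a member of the list, rose by 1.13. Border macrophages and monocytes (0.05, 13 members), T and NK cells (0.04, 4 members), endothelium and pericytes (-0.05, 13 members), meningeal fibroblasts (-0.02, 12 members) and ependymal cells (0.31, 9 members) had no member called. The same held for immediate early genes (-0.06, 14 members), extracellular matrix and perineuronal nets (-0.08, 12 members) and Y-linked and X-inactivation genes (-0.01, 6 members).

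Over all 17602 mouse genes tested with limma, 365 were called, 342 higher and 23 lower, of which 91 differed more than 2-fold. Camera called 11 lists higher and 7 lower, 2 of them with an estimated correlation, and fry called 8 higher and 1 lower. Without the libraries highest in blood and neutrophil markers, 272 genes were called higher and 1 lower. With the motor neuron level in the model, 285 were called higher and 2 lower.

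**Figure D1:**
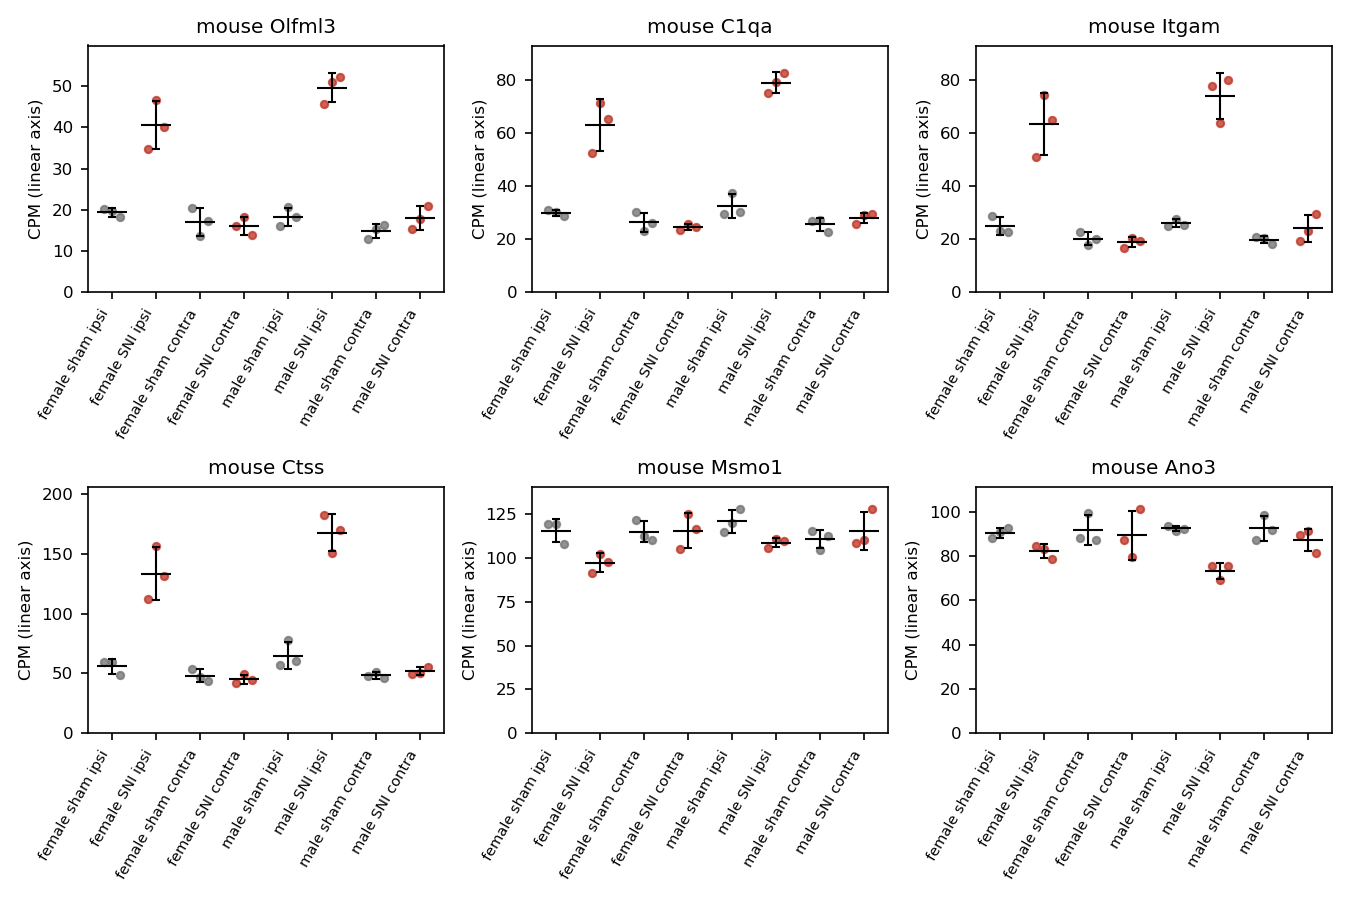
CPM on a linear axis for 6 mouse genes in each library (points, grey for sham and red for SNI) by sex, surgery and side, with the mean and SD of 3 libraries in black. Olfml3, C1qa, Itgam and Ctss stood higher in ipsilateral SNI libraries than in every other group, while Msmo1 and Ano3 differed by a small part of their level.

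**Figure D2:**
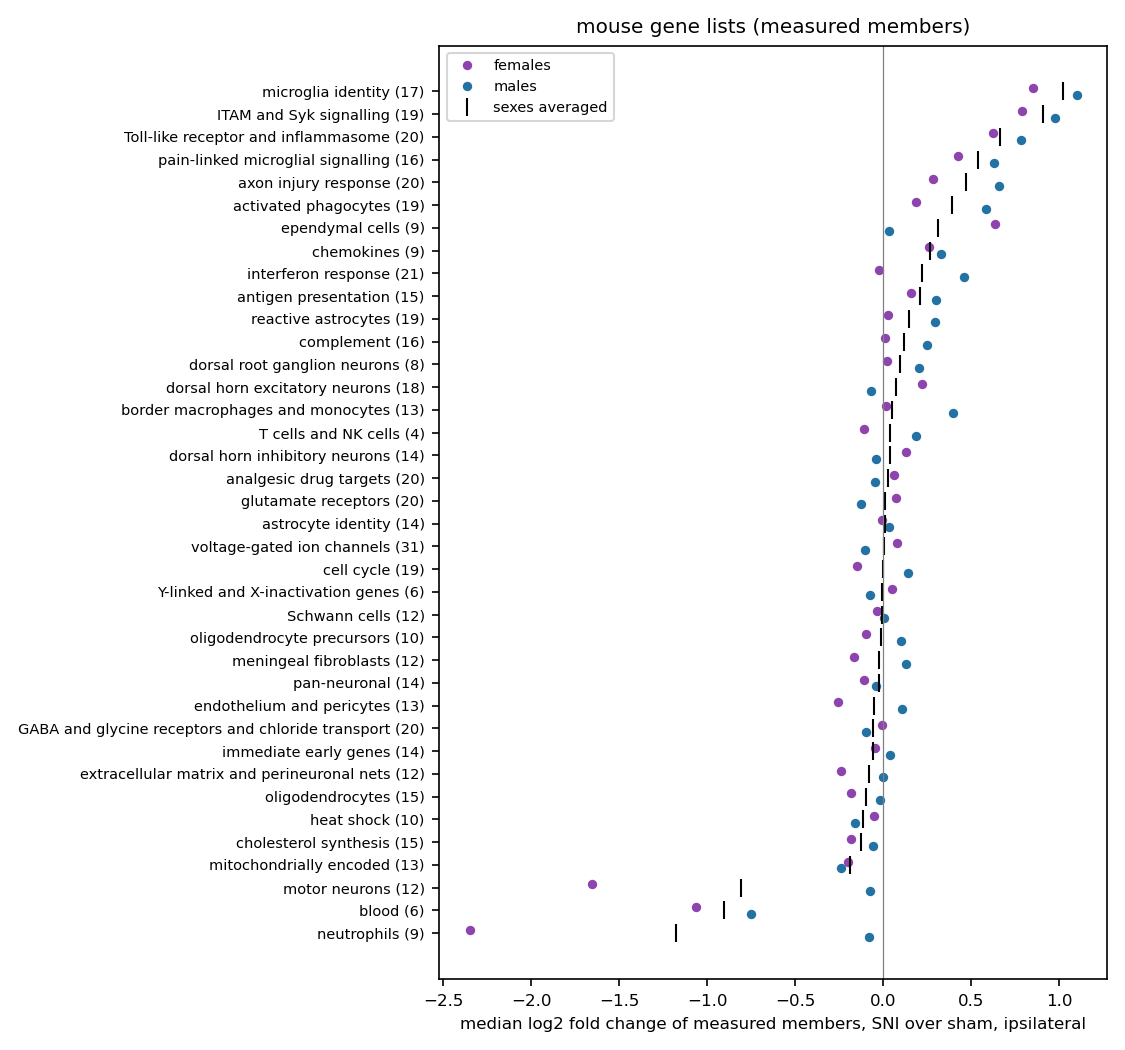
Median log2 fold change of SNI over sham on the ipsilateral side for 38 gene lists in mice, on the horizontal axis, with the number of measured members beside each name and the sexes as points. Microglia identity (median 1.02) and ITAM and Syk signalling (0.91) stand at the upper end, and motor neurons, blood and neutrophils at the lower end.

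The same comparison was then made within each sex of mice. In females the microglial genes Pld4 (0.99), Olfml3 (1.06), C1qa (1.06), Ly86 (1.47) and C1qc (1.18) led, and 13 of 17 microglia identity genes rose (median 0.85, adjusted p = 0.126 with an estimated correlation). Nr5a2, a nuclear receptor gene, fell by 1.61 (adjusted p = 0.0085) and Insig1, a brake on sterol synthesis, by 0.27 (adjusted p = 0.0496), both calls lost without sham replicate 1. In males Olfml3 (1.44), Pld4 (1.26), Rasal3 (1.53), Grn (0.89) and C1qa (1.28) led, and 16 of 17 microglia identity genes rose (median 1.10, adjusted p = 0.0779 with an estimated correlation). Ano3 (-0.34), Chgb, a secretory granule protein gene (-0.33), Malat1 (-0.54), Fam19a1 (-0.34) and Dpp10 (-0.28) were lowest by p in males. Motor neuron genes had a median of -1.66 in females, adjusted p = 0.167 with an estimated correlation, and were not called in males.

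In females 73 genes were called, 71 higher and 2 lower, and in males 363, 344 higher and 19 lower. Mouse libraries titled 49 to 56 had 75.4% to 76.1% of entries on genes, beside 71.4% to 74.7% in those titled 33 to 48. The later set holds male SNI replicates 2 and 3, no male sham library, and replicate 3 of each female group. The male effect and the sex by surgery interaction are thus partly confounded with it, and no fit had a term for this set. Of the genes called higher, 69 were shared, against 1.39 for independent lists, and 325 of the 344 male calls had the same sign in females. Of the genes called lower, 2 in females and 19 in males, 0 were shared, and 8 of the 19 had the same sign in females. Female calls numbered 42 without SNI replicate 2 and 108 without SNI replicate 1, and 19 with the motor neuron level in the model. Male calls fell to 195 without sham replicate 3 and numbered 478 with the motor neuron level in the model. Limma called 0 genes for the sex by surgery interaction, as did voom. An unadjusted p under 0.05 was found for 1793 genes with limma and 2491 with voom. The limma count is 10.2% of the genes tested, where no effect would give 5% on average. Irf7 stood at 2.79 and 2.80 CPM in female sham and SNI libraries and at 1.91 and 5.24 CPM in males, and its interaction of 1.42 had an adjusted p = 0.343; it was singled out after its values were seen.

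Camera called 18 lists with a positive and 4 with a negative interaction (male minus female log2 effect), and none with an estimated correlation (smallest adjusted p = 0.442). Interferon response genes had a median interaction of 0.60, with 10 of 21 members called adjusted over the list alone but 0 over all genes. Markers of other cells also shifted between the sexes: the mean log2 level of motor neuron genes differed by -1.49 after SNI in females and by -0.11 in males. Across genes, which are not independent replicates, female and male log2 fold changes had r = 0.229 and rho = 0.0167. Of 100 draws with surgery labels permuted within sex, 7 gave an r as high, up to 0.427, and rho reached 0.357.

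In rats, the genes called on the operated side were also mostly higher after SNI. ENSRNOG00000011947 went from 6.83 ± 0.77 to 23.3 ± 2.18 CPM in females and from 9.18 ± 1.5 to 26.7 ± 1.98 CPM in males (SD, n = 4 each; log2 1.66, SE 0.081, adjusted p = 9.2e-09). ENSRNOG00000017869 rose from 13.5 ± 1.83 to 50.3 ± 8.51 CPM in females and from 17.6 ± 2.89 to 57.9 ± 7.80 CPM in males (log2 1.81, SE 0.104, adjusted p = 6.2e-08). ENSRNOG00000007139 fell by 0.47 (adjusted p = 0.0033) and ENSRNOG00000015155 by 0.88 (adjusted p = 0.0040) on the log2 scale, the latter not called without the libraries titled 25 to 32. The files do not pair rat identifiers with names, so no rat gene is named and rat gene groups were not analysed here.

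Limma called 782 of 15929 rat genes, 749 higher and 33 lower, with 280 past 2-fold. The median absolute log2 fold change of called genes was 0.77, beside 0.70 in mouse. These medians depend on which genes could be called with 4 libraries per group in rat and 3 in mouse. They do not compare the size of the response between species. Females had 536 calls (526 higher) and males 330 (327 higher), with 309 higher in both against 10.8 for independent lists. All 327 genes called higher in males, and 525 of the 526 in females, had the same sign in the other sex. Of the genes called lower, 10 in females and 3 in males, 0 were shared, and 1 of the 3 had the same sign in females. The sex by surgery interaction gave 0 calls with limma and with voom, and 281 (1.76% of those tested) and 648 genes at an unadjusted p under 0.05. Across genes, female and male fold changes had r = 0.667 and rho = 0.332, and none of 100 permuted draws gave an r as high (highest 0.467), while the highest permuted rho, 0.440, lay above the rho of 0.332. Libraries titled 25 to 32, which are replicate 4 of every group, formed a set of their own in the deviations from group means, and without them 493 genes were called, 112 in males.

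**Figure D3:**
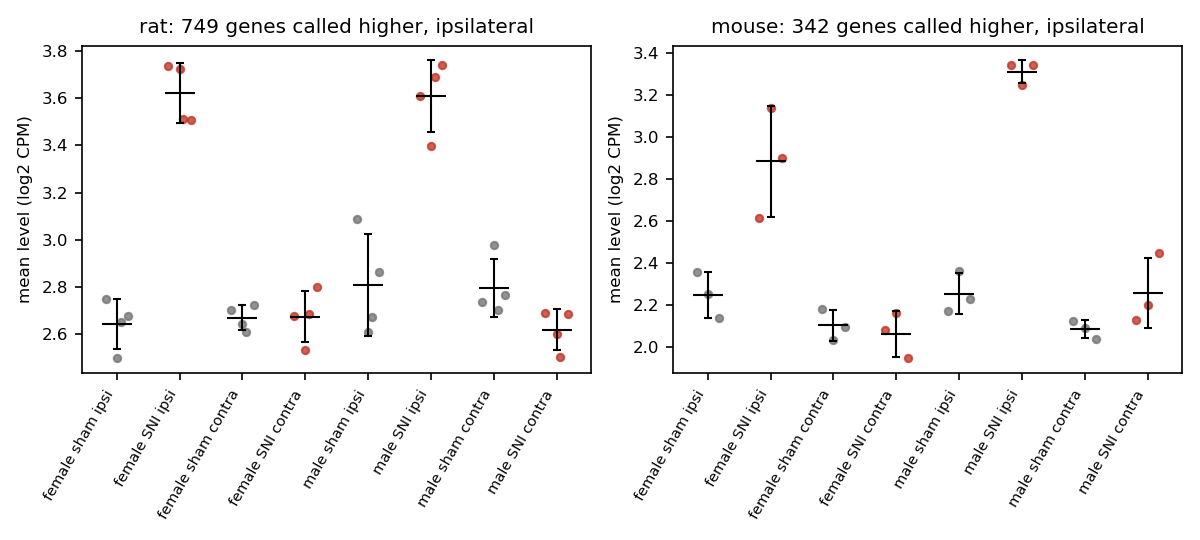
Mean log2 CPM of the genes called higher ipsilaterally in each species (749 in rat, 342 in mouse) in every library, grey for sham and red for SNI, with group mean and SD in black. These genes were chosen on the ipsilateral libraries, so the ipsilateral groups test nothing. Contralateral libraries were not used in the choice but may share animals with the ipsilateral ones. Rat contralateral means lie between 2.62 and 2.80, and mouse ones between 2.06 and 2.26.

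The contralateral comparison asked whether the unoperated side responded. Olfml3 had a log2 difference of 0.10 (SE 0.109) and C1qa of 0.02 (SE 0.070) between contralateral SNI and sham libraries in mice, and Atf3 one of -0.02 (SE 0.174). Microglia identity genes had a median of 0.06 averaged over the sexes, called by camera, with an adjusted p = 0.949 under an estimated correlation. In males it was 0.23, with interferon genes at 0.41 and neutrophil genes at 1.52, each with an adjusted p = 0.508 under an estimated correlation. Among the markers of other cells, contralateral motor neuron genes had a median of 0.41 (adjusted p = 0.949 with an estimated correlation). In rats, ENSRNOG00000011947 stood at 0.03 (SE 0.111) and ENSRNOG00000017869 at -0.09 (SE 0.075).

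Limma called 0 contralateral genes in either species, averaged or in either sex. Voom also called 0 averaged over the sexes. Genes at an unadjusted p under 0.05 numbered 290 in rat and 336 in mouse with limma, and 439 and 764 with voom; by sex, limma gave 186 (female) and 523 (male) in rat and 429 and 706 in mouse. Without contralateral female SNI replicate 1, 43 genes were called in female mice, and without male SNI replicate 1, 2 in males.

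Side by surgery asked whether the injury effect itself differed between the sides. In mice C1qa (1.15), C1qb (1.16), C1qc (1.23), Ctss (1.31), the inhibitory receptor gene Lag3 (1.66) and Rasal3 (1.30) had larger effects ipsilaterally, each with an adjusted p = 2.0e-06. Of 17 microglia identity genes 15 were called (median 0.85, adjusted p = 0.0020 with an estimated correlation), as were 11 of 19 ITAM and Syk genes (0.80, adjusted p = 0.0057) and 4 of 20 axon injury genes (0.42, adjusted p = 0.0025). Motor neuron genes had a median of -1.25 there, with an adjusted p = 0.109 under an estimated correlation. In all, 115 of 18058 mouse genes were called, 114 with a larger effect ipsilaterally, and 556 of 16248 rat genes, 551 of them larger ipsilaterally. ENSRNOG00000017869 led the rat comparison with 1.89 (SE 0.132, adjusted p = 2.6e-10).

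Within SNI mice, all 17 microglia identity genes were higher ipsilaterally (median 1.19, adjusted p = 0.0030 with an estimated correlation), as were 15 of 20 axon injury genes (0.55, adjusted p = 0.0030). Motor neuron genes were lower, 7 of 12 called, with a median of -1.29 and an adjusted p = 0.121 under an estimated correlation. There were 1237 calls in mouse (643 higher, 594 lower) and 1369 in rat (1011 higher, 358 lower). The balance was not stable: without the libraries titled 25 to 32, rat calls were 783 higher and 58 lower, and mouse totals ran from 614 to 2100 when 1 library was left out. With the motor neuron level in the model, mouse calls numbered 331, of which 5 were lower ipsilaterally. In sham mice the microglia identity genes had a median side difference of 0.26, called by camera, with 15 of 17 called adjusted over the list alone but 0 over all genes (adjusted p = 0.163 with an estimated correlation). Limma called 0 genes between sham sides in both species, with 121 genes in rat (0.745%) and 742 in mouse (4.11%) at an unadjusted p under 0.05.

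Males and females were compared in ipsilateral sham libraries. In mice the Y-linked genes Kdm5d (8.62), Ddx3y (9.14), Uty (8.23) and Eif2s3y (8.88) were higher in males, and Xist, the RNA that silences an X chromosome, was lower (-10.94). Ddx3y stood at 0.137 ± 0.0465 CPM in females and 109 ± 3.13 CPM in males, and Xist at 752 ± 70.1 and 0.326 ± 0.080 CPM (SD, n = 3 each). The sizes of these log2 values depend on the prior count, because the lower group holds few reads. Limma called 10 mouse genes (6 higher in males) and 17 rat genes (12 higher in males).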

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

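The tests of explanations and the counts of other splits in this part were written down after the results they bear on had been seen; the interaction tests had been fixed before.

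Among 80 sets of 4 libraries examined for a value far from the other 3, 7 had one, and chance gives about 1 in 20. Rat female ipsilateral sham replicate 4 held 49.4 M gene reads, beside 27.1 to 27.2 M in the others of its group. Rat male contralateral sham replicate 1 held 38.6 M, beside 25.3 to 25.9 M. Rat male contralateral SNI replicate 4 had 25.2% of its reads in no feature (21.4% to 21.8% in the others), and rat male ipsilateral SNI replicate 4 had 17.4% without a unique position (14.8% to 15.2%). In rat female contralateral SNI replicate 4 the 10 highest genes took 9.82% of gene reads, beside 12.4% to 12.8%. ENSRNOG00000011947 stood at 9.77 CPM in rat male contralateral sham replicate 3 (7.43 to 7.76 CPM), and ENSRNOG00000015155 at 47.9 CPM in rat female contralateral sham replicate 2 (11.2 to 14.9 CPM). Groups of 3 mouse libraries were not examined this way.

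The injury effect differed between sides by the interaction test for 556 rat and 115 mouse genes. Between the sexes of mice, camera called 22 gene lists for the interaction, and 0 of them with an estimated correlation.

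Atf3 and Sprr1a rose in mouse ipsilateral SNI libraries except female replicate 1, where both stood at sham level. More ventral tissue in the SNI libraries stays open. The motor neuron list differed by -1.49 (SE 0.427) in females and by -0.11 (SE 0.502) in males. These values cannot decide it, because nerve injury may itself change the motor neuron markers. Dorsal root ganglion tissue stays open: its marker list was higher after SNI in males, by 0.384 (SE 0.0737), and differed by -0.0769 (SE 0.167) in females, whose replicate 1 lacked both transcripts. Injured motor neurons inside the dissected piece also stay open. Within each sex the slope of the 2 genes on the motor neuron level was 3.96 (SE 2.81, exact permutation p = 0.25) over 6 SNI libraries, 8.36 in females and -0.740 in males.

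Microglia identity genes were higher ipsilaterally than contralaterally in sham mice, by 0.27 over mean log2 levels and in 6 of 6 neighbouring pairs. Also higher in 6 of 6 pairs were the activated phagocyte (0.27), ITAM and Syk (0.27), pain-linked signalling (0.23), Toll-like receptor (0.19) and analgesic target (0.08) lists. The neutrophil (1.12), blood (0.57) and cell cycle (0.28) lists, among others, were higher in 5 of 6 pairs. The highest neutrophil pair stood at 4.54. A sham library that is an SNI library by mistake is argued against by the microglia identity list. Its lowest SNI level lay 0.415 above its highest sham level, beside an SD of 0.113 within ipsilateral sham groups. The ITAM and Syk list also had a gap (highest sham 2.19, lowest SNI 2.47). The activated phagocyte (3.76 and 3.68), pain-linked signalling (3.41 and 3.35) and Toll-like receptor (1.46 and 1.43) lists overlapped. A lower share of neurons would raise astrocyte genes alike. As the whole cause it is argued against by a side difference of 0.0299 (SE 0.0255) in the astrocyte list. A smaller contribution stays open. The pan-neuronal list differed by -0.093 (exact permutation p = 0.26) and the oligodendrocyte list by 0.127 (exact permutation p = 0.18). Chance side labels stay open. For the microglia identity list the exact permutation p of 0.01 is 0.19 adjusted over 38 lists. The smallest possible p, 0.005 over 400 arrangements, is also 0.19 for a lone list, so the test could hardly pass. The design has no unoperated group, so an effect of sham surgery itself was not tested, nor was a higher share of blood cells, and either may be present or not.

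The 342 genes called higher in mice had a larger effect in males than in females, by 0.413 on the log2 scale over mean levels. Chance sex labels stay open, with an exact permutation p = 0.1 (0.413 was reached by 40 of 400 arrangements). Without the female SNI library with the lowest level the difference was 0.286, beside 0.422 for the same measure with all libraries, so whether that library alone makes the difference cannot be told apart from a sex difference. In rats the corresponding difference was -0.167 (exact permutation p = 0.305). Male SNI replicates 2 and 3 also belong to the set titled 49 to 56, which holds no male sham library. The mean log2 level of these genes was 3.25 and 3.34 in them and 3.34 in ipsilateral replicate 1, outside the set. A sex difference in mice therefore stays a hypothesis.

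Other splits of the same libraries were counted for each of 22 comparisons, the real split included. A share under 0.05 counts against chance for that comparison alone, because no share was adjusted over the comparisons. For side by surgery, labels were exchanged on each side separately, so libraries that may share an animal could receive different surgeries. In rat, only the real split, 1 of 100, gave as many genes for the ipsilateral effect averaged over the sexes (782 in the real split and 99 in the highest other). The share was also 1 of 100 for side by surgery (556 and 110) and for the sides within SNI (1369 and 5). It was 1 of 35 in males (330 and 1) and for males against females (17 and 0). A share of 1 of 35 is the smallest those splits allow and alone does not exclude chance among 22 comparisons. Chance cannot be excluded by this count for rat females, where 2 of 35 splits gave as many genes (536 in the real split, 617 in the highest other). That split exchanged sham replicates 1 and 3 with SNI replicates 1 and 4. In mouse, the share was 1 of 100 for the averaged ipsilateral effect (365 and 249) and for the sides within SNI (1237 and 1136). For side by surgery 4 of 100 splits gave as many genes as the real 115, and 3 other splits gave 1741, 730 and 224. Chance is not excluded there. A split with many times the real count points to a structure of the samples, and what makes it was not tested.

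In mouse, 3 libraries against 3 make 10 splits, too few for a share under 0.05. There the real counts and highest others were 73 and 0 in females, 363 and 25 in males, 0 and 0 for contralateral females, 0 and 1 for contralateral males, and 10 and 12 for males against females. For comparisons with 0 calls every split gave as many. The highest other split gave 15 (rat) and 776 (mouse) for sex by surgery, 30 and 651 for the averaged contralateral effect, 297 and 97 for the sides within sham, and 0 and 5 for contralateral rat females and males, in 35 of 35 splits each.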

How the results depend on the processing

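The minimum fold, the set and component terms, the motor neuron level, and the fits without titles 25 to 32 or without the libraries highest in blood and neutrophil markers were chosen after seeing the data; the other alternatives were fixed before. The quasi-likelihood and Wald tests on counts, their minimum-fold test, a surrogate variable and every alternative for the species comparisons were not run. Where a count moved by over 1.5 times, the values follow, and the cause was not tested. The counts they are set beside were 782 (averaged), 536 (females), 330 (males), 556 (side by surgery), 1369 (SNI sides) and 17 (sexes) in rat, 365, 73, 363, 115, 1237 and 10 in mouse, and 0 for the contralateral and sham side comparisons. A minimum fold of 1.2, which is stricter by construction, left 362 rat calls averaged, 289 in females, 194 in males, 300 for side by surgery, 463 between SNI sides and 7 between sexes, and 126, 26, 132, 55 and 206 in mouse (averaged, females, males, side by surgery, SNI sides). Without titles 25 to 32, which leaves fewer libraries, rat calls were 493 averaged, 112 in males, 841 between SNI sides and 8 between sexes. A term for that set gave 1 contralateral call in rat males and 27 calls between rat sexes, and the first component of the deviations 51. Voom gave 645 calls in rat males. The motor neuron level left 19 calls in mouse females and 331 between SNI sides. With no filter, 1 gene was called between sham sides in mouse. A block of neighbouring title numbers raised the calls between SNI sides to 2396 in rat (1349 higher, 1047 lower) and 2355 in mouse (1166 and 1189) and gave 712 and 167 for side by surgery and 0 between sham sides. Neighbours are not stated to share an animal: 14 of 16 rat and 10 of 12 mouse pairs deviated together with a correlation over 0.1, the lowest being -0.514 and -0.0734, and 14 and 9 ipsilateral libraries correlated best with their neighbour. Of 18 lists called by camera, 2 were called with an estimated correlation and 9 by fry. The correlation of mouse female and male effects was 0.127 over genes above the median level, against 0.229. Leaving out each library gave 10 to 39 calls between rat sexes (lowest without female sham replicate 3, highest without male sham replicate 2). In mouse it gave 195 to 367 in males, 42 to 108 in females, 0 to 1 for sex by surgery, 0 to 1 contralaterally averaged, 0 to 2 in contralateral males, 0 to 43 in contralateral females, 0 to 1 between sham sides and 614 to 2100 between SNI sides (without contralateral female SNI replicates 3 and 1). The correlations ranged from 0.543 to 0.704 in rat and from 0.0931 to 0.351 in mouse. Over the other alternatives, calls ranged from 362 to 1152 averaged in rat and from 126 to 425 in mouse, and the direction of the calls stayed mostly upward. Genes that turned sign, none of them called, did so with the motor neuron level in the model: Olig2 0.0401, Lck -0.0381, Zap70 -0.0042, Lum 0.0225, Col1a1 0.311, Col1a2 0.221 and Rsph1 -0.0863. The motor neuron list, called lower by camera in the main fit, also turned sign there (camera adjusted p = 0.68), because that term removes its difference by construction. Without the libraries highest in blood and neutrophil markers Col1a2 was 0.0131. Depth limits the lowest genes: the filter left out those under about 10 counts.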

Other observations

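The comparisons in this part were chosen after the data had been seen.

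Xist, the RNA that silences an X chromosome in females, was present at low level in some male mouse libraries. It stood at 0.271 to 0.418 CPM in male ipsilateral sham libraries and at 0.761, 2.34 and 2.28 CPM in ipsilateral SNI replicates 1, 2 and 3. On the contralateral side, SNI replicates 2 and 3 stood at 2.43 and 3.61 CPM and replicate 1 at 0.298 CPM, while female ipsilateral sham libraries averaged 752 CPM. Male SNI replicates 2 and 3 are titled 49 to 52, between female libraries in title order. The male sham libraries and SNI replicate 1 are titled 33 to 40. Surgery and title order are thus mixed here, and the cause was not tested. Genes on the opposite strand overlap 11.5% of the Xist exon length, and the strand setting is not given.

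Atf3, which is induced in injured neurons, stood at 36.1 and 15.2 CPM in female ipsilateral SNI replicates 2 and 3, at 74.5, 55.3 and 45.3 CPM in male replicates 1, 2 and 3, and at 1.02 CPM in female replicate 1. Sprr1a followed the same libraries, at 47.1, 20.4, 76.1, 85.4, 58.5 and 0.229 CPM. Microglial genes did not share that gap: C1qa stood at 52.4 CPM in female replicate 1, the lowest of the ipsilateral SNI libraries, where the highest ipsilateral sham library had 37.6 CPM. By sex, Atf3 had log2 fold changes of 2.83 in females (adjusted p = 0.512) and 5.35 in males (adjusted p = 0.0474), and the interaction had an adjusted p = 0.577.

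Markers of some cell types varied widely between mouse libraries of 1 group. The SD of mean log2 levels within groups was 1.35 for neutrophil genes, 0.616 for meningeal fibroblast genes, 0.598 for blood genes, 0.585 for ependymal genes, 0.570 for Schwann cell genes and 0.543 for motor neuron genes, beside 0.145 for microglia identity genes. Ependymal genes were lower ipsilaterally in sham mice by 0.551 (exact permutation p = 0.01, 0.19 adjusted over 38 lists, where a lone list could not pass 0.05).

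A hypothesis was that the contralateral side carries a weak share of the injury response. It was read on the 722 rat and 322 mouse genes of the ipsilateral lists measured there, against a bound of 0.1. The lists were chosen on ipsilateral libraries, which may share animals with the contralateral ones. In male rats a share at the bound is argued against by a mean contralateral difference of -0.165 (SE 0.0726), over 2 SE below 0.1. Its exact permutation p = 0.0286, the smallest that 70 arrangements allow, is for a difference from 0 and was not adjusted over the groups. Of the 722 genes 18.8% lay above 0, and what lowered the others was not tested. In female rats the mean was 8.3e-04 (SE 0.0562), in female mice -0.0449 (SE 0.0778) and in male mice 0.191 (SE 0.101). A weak share may be present in these groups and cannot be told apart from none, because the bound lies within 2 SE of each mean.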
